A study of Mus musculus with 6 samples.

How the data were processed

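RNA sequencing was done on 6 libraries of mouse bone marrow-derived macrophages, 3 untreated and 3 given IFN-γ for 3 h. Per the labels' protocols, bone marrow cells were grown in wells with 10% serum, 1% antibiotics and 20 ng/mL M-CSF, with fresh medium on day 3 and day 5. RNA was extracted with Trizol and libraries were made with the KAPA stranded mRNA kit, per the labels' protocols. The aligner was HISAT2 and the build mm10, per the submitters' processing notes, with no version given. The counting tool, its use of strand and its treatment of reads that map to several places are not given in the sources used here. Each table lists 36706 genes or transcribed features, with exon coordinates and length. The coordinates are not those of mm10: of 35271 symbols also in the RefSeq table of assembly GRCm38.p6, 601 (1.7%) had the same start and end. Coordinates are therefore printed as the tables give them, with the build unnamed.

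Per the file headers, each table gives a deposited count, TPM and FPKM per gene. The counts deposited by the authors are whole numbers, not normalized, and were the values tested. The TPM and FPKM columns deposited by the authors were recomputed from the counts and lengths to within 7.3e-11, and were not tested. Total counts ran from 28133342 to 34233607 per library. Floors of 3 counts cover counting error only, and the labels name no molecular identifiers. The ± values are SDs between libraries or standard errors from the fit, which include the spread between libraries. Every entry named a gene, 75 entries lay on unplaced sequences, 0 mitochondrial genes were listed, and 1 symbol occurred more than once and was named by its identifier.

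Groups were taken from the treatment label. Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3: low counts were removed with filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and the group effect was tested by glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over 12968 genes and a threshold of 0.05. CPM are counts scaled to library size with the TMM factors. The standard error is the log2 fold change divided by the square root of F. The common biological coefficient of variation was 0.089. Every pair of replicates differed by more than sampling noise (chi-square per degree of freedom from 2.05 to 81.12), so none was treated as a library deposited more than once; this does not show that they are separate cultures.

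Before the data were examined, 32 gene lists were fixed, holding 804 members, of which 778 were listed in the tables. They were tested with camera at a preset correlation of 0.01 on log2 CPM, with adjustment over the 30 lists with at least 3 members tested, and again with an estimated correlation and with fry. Of the 14 lists higher by camera, 4 kept their call with an estimated correlation: interferon-inducible GTPases, type I interferon response genes, NF-κB, and cytosolic sensing. The cell cycle list did not keep its call. The named genes were also set in advance. They are the 12 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM and groups that do not overlap, 14 genes named whatever their result, and up to 3 called members per list with the largest changes and at least 1 CPM, or the 2 most abundant members of a list with none called. Genes named outside this rule are said to be so. Results of some genes that the rule names, or that lie near Acod1, are not reported here.

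On data simulated from these libraries over 12769 genes, with 50 genes changed at each fold, the test recovered 64% of 1.5-fold, 86% of 2-fold and 98% of 4-fold changes, and 9 of 141 calls (6.4%) were false. Alternatives were RLE, upper quartile and total count scaling, no filter, a filter of 5 CPM in 3 samples, DESeq2 1.42.0, limma-voom, the robust fit, the replicate number as a block, a threshold of 0.01, a test against 2-fold, predicted genes left out, and each library left out. Removal of 6 entries that differed together in 1 untreated library, most of them ribosomal RNA-like, and removal of each library's trend on exon length (lowess, span 0.5) were added after seeing the data. The 107 named genes were matched to GENCODE M21 transcripts by symbol. Of these, 10 shared at least 10% of their 50-base stretches with another gene, among them Tgtp1, Serpina3f, Serpina3g, Ifi205 (18.6%), Ifi203 (12.2%), Tlr6 (12.3%), Cycs (25.9%) and Mpc1 (11%). Exons of 4 named genes (Arg1, Cd163, Mpc1 and Uqcrc2) overlapped a gene on the other strand by at least 10% of their length. These shares are of sequence or exon length, not of counts, so the part of a count in doubt can be larger or smaller. Cd163 had a mean of 33.3 counts, against 231.7 for the gene it overlaps, and Uqcrc2 had 2929 against 87.2. Il27, with an overlap of 9.8%, had 493.8 against 5714.3. Permutations and figures used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.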

Results

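Gene expression was profiled by RNA sequencing in bone marrow-derived macrophages of wild-type mice, which are macrophages grown from bone marrow cells in the growth factor M-CSF. The 6 libraries fell into 2 groups of 3: macrophages left untreated and macrophages given interferon-gamma (IFN-γ), a cytokine that activates macrophages, for 3 h. The stated purpose was to learn how IFN-γ induces ACOD1, the enzyme that makes itaconate from cis-aconitate. The tables held 28133342, 28709235 and 31173432 counts in untreated replicates 1, 2 and 3, and 34233607, 32628170 and 33106160 counts in IFN-γ replicates 1, 2 and 3. A floor of 3 counts in 1 library corresponded to between 0.089 and 0.101 CPM, counts scaled to library size with the TMM factors. Nothing in the labels says that the replicates came from separate mice or cultures, so the p-values measure only the spread between these samples, which may be technical.

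IFN-γ raised a set of guanylate-binding proteins, immunity-related GTPases, chemokines and the itaconate enzyme gene Acod1 by factors of 32 or more, while falls were smaller. Of 12968 genes tested, 2539 were higher and 2176 lower with IFN-γ (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At 2 times or more, 800 genes were higher and 251 lower. At 8 times or more, 117 genes were higher and 1 was lower, and 37 genes were at least 32 times higher. The 1 gene lower by 8 times or more was B3galt5, a galactosyltransferase gene named after its values were seen, at 1.66 ± 0.251 CPM untreated and 0.2 ± 0.0952 CPM with IFN-γ (mean ± SD, n = 3 each). The groups did not overlap for 6496 genes, or 50.1%, where chance alone gives 10% on average for 3 samples against 3. Genes measured in the same libraries can shift together, so the share by chance in a given set of libraries can lie far from 10%. The balance of the smaller changes depended on the scaling of the libraries. The main TMM scaling put 53.8% of called genes on the higher side. Upper quartile scaling shifted the median log2 fold change by -0.147 and put 30.6% there, with 4097 genes lower and 415 at least 2 times lower. Total counts alone shifted it by -0.17 and put 26.9% there, with 1666 genes higher, 4520 lower and 448 at least 2 times lower.

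Acod1 rose from 32.1 ± 0.542 CPM in untreated macrophages to 1947 ± 72.9 CPM with IFN-γ (mean ± SD, n = 3 each). The log2 fold change was 5.92 ± 0.07 (SE), or 60.7-fold, with an adjusted p of 1.3e-09 in edgeR's quasi-likelihood test. Its counts were 964, 932 and 1100 in the untreated libraries and 65918, 58491 and 59114 with IFN-γ. Over all scalings, filters, left-out libraries and tests, apart from that against 2-fold, the log2 fold change stayed between 5.75 and 5.95. The tables place Acod1 on chromosome 14, plus strand, from 103284448 to 103294009, with 5 exons that hold 2588 bases. These are the coordinates of the tables, which name no genome build and do not match mm10, the build named in the submitters' processing notes.

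The pathway that carries the IFN-γ signal changed with the treatment. Of 24 tested genes of the IFN-γ receptor and JAK-STAT list, 21 rose and 1 fell, both over all genes and adjusted over the list alone (camera adjusted p = 1.12e-11, and adjusted p = 0.0818 with an estimated correlation). Irf1, an interferon-response transcription factor gene, rose from 33.1 ± 0.605 to 941 ± 14.2 CPM, a log2 fold change of 4.83 ± 0.06. Irf8, a transcription factor gene of the macrophage lineage, rose by 2.03 ± 0.05. The feedback inhibitors Socs1 and Socs3 rose by 4.94 ± 0.11 and 4.54 ± 0.07. The kinase gene Jak2 rose by 1.79 ± 0.06. The receptor chain gene Ifngr1 fell by 0.35 ± 0.05 on the log2 scale, from 159 to 124 CPM. Ifngr2 was at 134.5 and 160.5 CPM, a log2 fold change of 0.25 ± 0.06 with an adjusted p of 0.00859, which lost its call with upper quartile scaling (0.11) and total counts (0.08). Jak1 rose by 0.43 ± 0.08 and lost its call with total counts alone (0.26, adjusted p = 0.0533). Ifng and Ifnb1 were chosen after their values were seen. Ifng, the gene of the ligand, had 0 counts in all 6 libraries, below the floor of 3 counts. Ifnb1, the gene of a type I interferon, had 1 count in each untreated library and 12, 15 and 15 counts with IFN-γ.

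**Figure D1:**
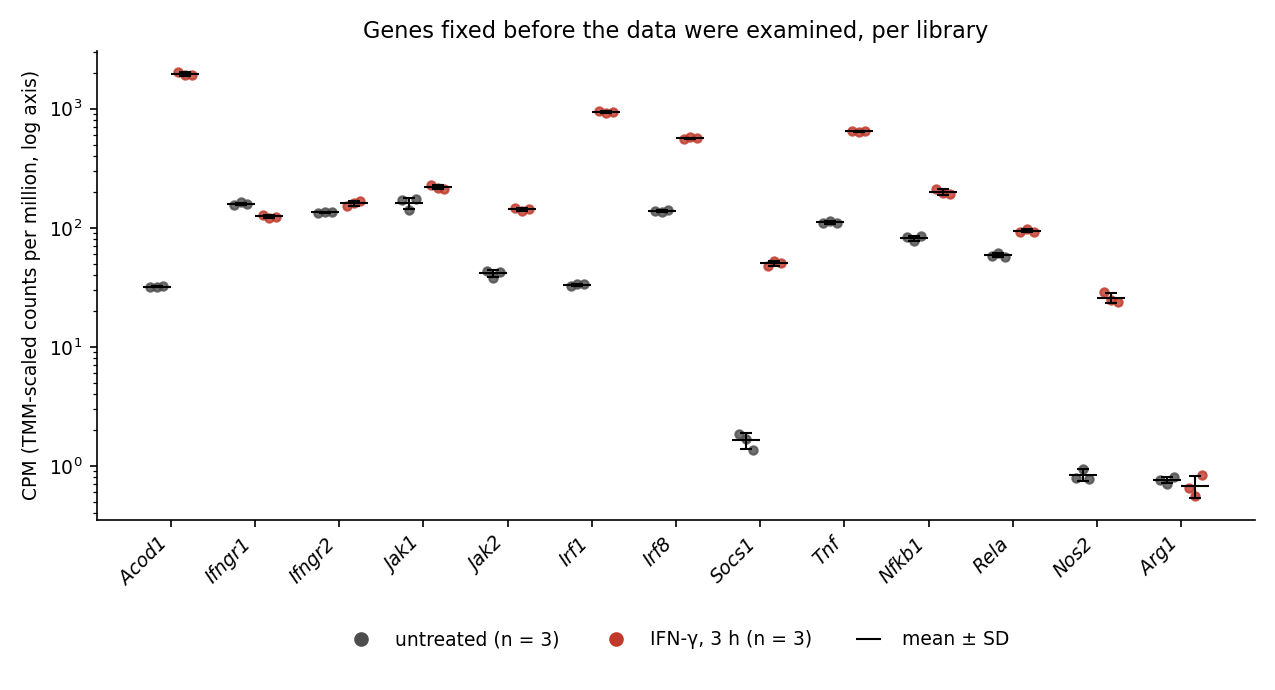
CPM on a log axis in each of the 6 libraries for 13 genes named before the data were examined, with grey points for untreated and red points for IFN-γ at 3 h, and black bars for the mean ± SD of 3 libraries. Acod1 lay near 32.1 CPM in untreated and 1947 CPM in IFN-γ macrophages, while Arg1 stayed under 1 CPM in both groups.

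The 12 largest rises lay between log2 fold changes of 6.47 and 8.75. Serpina3f and Serpina3g, a pair of serpin genes on chromosome 12, rose by 8.75 ± 0.14 and 8.02 ± 0.09 on the log2 scale. Cxcl9 and Cxcl10, chemokines that draw T cells, rose by 8.23 ± 0.14 and 6.47 ± 0.08, to 345 ± 20.0 and 1969 ± 22.1 CPM. The immunity-related GTPase genes Tgtp1 and Iigp1 rose by 7.83 ± 0.17 and 7.79 ± 0.09, and the predicted gene Gm4841 by 7.72 ± 0.26. The guanylate-binding protein genes Gbp4, Gbp5 and Gbp2 rose by 7.71 ± 0.10, 7.48 ± 0.09 and 7.04 ± 0.08. Gbp2 reached 2856 ± 35.0 CPM from 21.7 ± 1.16. Clic5, a chloride intracellular channel gene, rose by 6.53 ± 0.25, and Calhm6, a calcium homeostasis modulator gene, by 6.47 ± 0.11. The untreated counts behind 4 of these folds were small, at 0, 4 and 3 for Gm4841, 1, 5 and 4 for Clic5, 3, 7 and 8 for Tgtp1, and 7, 11 and 5 for Serpina3f. Part of the sequence of some of these genes is shared with relatives, so their counts are uncertain as single genes. Of the 50-base stretches in their transcripts, 81.2% of Tgtp1 (mainly with Tgtp2), 15.5% of Serpina3g and 10.6% of Serpina3f occurred in another gene.

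The 8 largest falls were smaller than the largest rises. S1pr1, a sphingosine-1-phosphate receptor gene, fell from 42.7 ± 1.06 to 6.53 ± 0.104 CPM, a log2 fold change of -2.71 ± 0.07. Thbd, the gene of thrombomodulin, had a log2 fold change of -2.41 ± 0.12, and the chemokine receptor genes Cxcr4 and Cx3cr1 had -2.31 ± 0.10 and -1.92 ± 0.09. Bmf, a pro-apoptotic gene of the BCL2 family, fell with a log2 fold change of -1.99 ± 0.14. The log2 fold change was -1.755 ± 0.14 for 2900026A02Rik, -1.73 ± 0.06 for Dtx4, a Deltex E3 ubiquitin ligase gene, and -1.70 ± 0.10 for Tfap4, a transcription factor gene.

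Interferon-response lists rose almost in full. All 22 interferon-inducible GTPase genes tested rose at least 2 times, with a median log2 fold change of 5.75 (camera adjusted p = 9.38e-25, and adjusted p = 0.0109 with an estimated correlation). Of 36 type I interferon response genes, 35 rose, 29 of them at least 2 times, and none fell (camera adjusted p = 9.38e-25, and adjusted p = 0.0109 with an estimated correlation). The counts adjusted over the list alone were again 22 and 35. Among them Ifi205, Ifit2 and Rsad2 rose by 4.18 ± 0.11, 3.98 ± 0.07 and 3.10 ± 0.07. Cytosolic sensing and inflammasome genes rose in 21 of 26 cases, or 22 with 1 lower when adjusted over the list alone (camera adjusted p = 3.81e-13, and adjusted p = 0.0201 with an estimated correlation). Nod1, a sensor of bacterial peptidoglycan, Zbp1, a sensor of Z-form nucleic acids, and Ifi203 rose by 3.44 ± 0.11, 3.16 ± 0.11 and 2.94 ± 0.06.

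**Figure D2:**
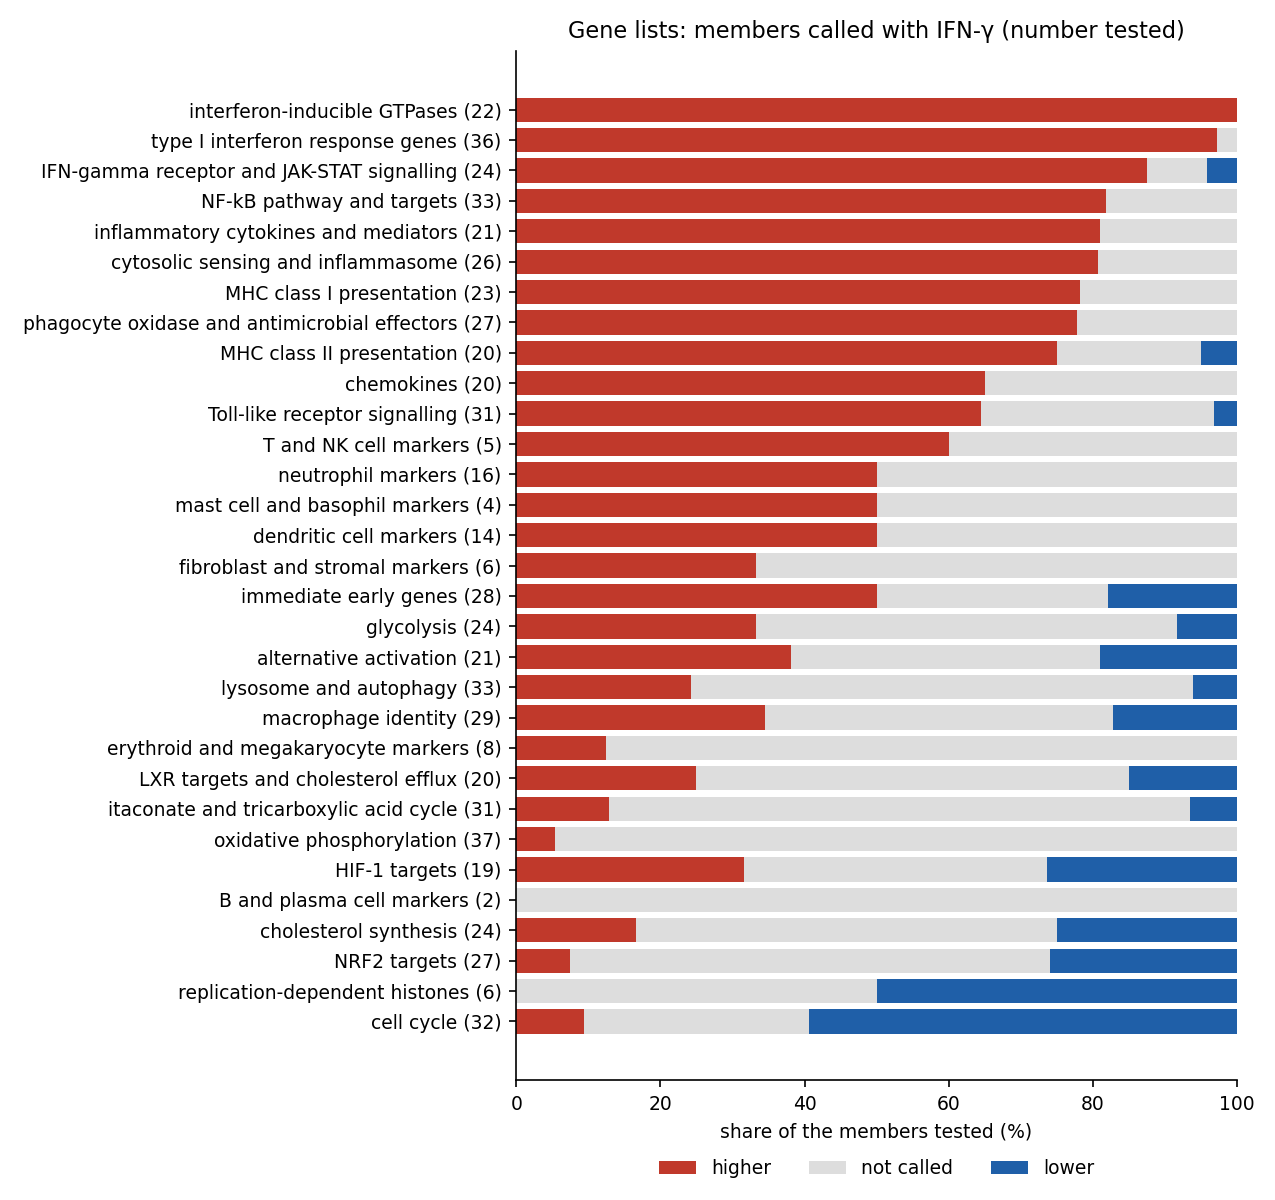
Share of the tested members of each fixed gene list, in percent, that were higher (red), lower (blue) or not called (grey) with IFN-γ, with the number tested in parentheses after each list's name. All 22 interferon-inducible GTPase genes were higher, and 19 of 32 cell cycle genes were lower.

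Antigen presentation genes rose on both arms. Of 23 MHC class I presentation genes, 18 rose and none fell, or 20 when adjusted over the list alone (camera adjusted p = 2.87e-10, and adjusted p = 0.123 with an estimated correlation). Nlrc5, the transactivator of class I genes, rose by 3.22 ± 0.14, the peptide transporter gene Tap1 by 2.85 ± 0.07 and the loading factor gene Tapbpl by 2.54 ± 0.06. Of 20 MHC class II and co-stimulation genes, 15 rose and 1 fell, or 16 and 1 when adjusted over the list alone (camera adjusted p = 4e-07, and adjusted p = 0.122 with an estimated correlation). Ciita, the transactivator of class II genes, rose from 0.773 ± 0.108 to 25.4 ± 2.94 CPM, by 5.03 ± 0.14. Cd40, a co-stimulatory receptor gene, and Cd274, the gene of the inhibitory ligand PD-L1, rose by 4.49 ± 0.08 and 4.19 ± 0.09.

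Inflammatory genes rose as groups. Of 33 NF-κB pathway and target genes, 27 rose and none fell, or 28 when adjusted over the list alone (camera adjusted p = 5.37e-15, and adjusted p = 0.0109 with an estimated correlation). The adhesion genes Vcam1 and Icam1 and the signalling adaptor gene Traf1 rose by 3.37 ± 0.12, 2.92 ± 0.06 and 2.24 ± 0.08. Nfkb1 and Rela, which encode NF-κB subunits, rose by 1.28 ± 0.07 and 0.68 ± 0.06. Tnf rose from 111.5 ± 3.15 to 644 ± 4.48 CPM, by 2.53 ± 0.06. Of 21 inflammatory cytokine and mediator genes, 17 rose and none fell, or 19 when adjusted over the list alone (camera adjusted p = 1.17e-12, and adjusted p = 0.0888 with an estimated correlation). Ptgs2, the gene of cyclooxygenase-2, rose by 5.31 ± 0.09, Nos2, which makes nitric oxide, by 4.94 ± 0.13, and Il27 by 4.81 ± 0.16. Of 20 chemokine genes, 13 rose and none fell, or 14 when adjusted over the list alone (camera adjusted p = 8.02e-07, and adjusted p = 0.323 with an estimated correlation). Ccl12 rose by 4.03 ± 0.13, after Cxcl9 and Cxcl10.

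Of 27 phagocyte oxidase and antimicrobial genes, 21 rose and none fell, over all genes and adjusted over the list alone (camera adjusted p = 3.58e-10, and adjusted p = 0.122 with an estimated correlation). After Nos2, the Fc receptor gene Fcgr4 and the complement gene C3 had the largest rises, 2.33 ± 0.09 and 2.14 ± 0.14. Of 31 Toll-like receptor signalling genes, 20 rose and 1 fell, or 21 and 1 when adjusted over the list alone (camera adjusted p = 2.54e-07, and adjusted p = 0.129 with an estimated correlation). None of them fell without untreated replicate 1 or 3 or without any 1 IFN-γ replicate. Tlr9, Tlr2 and Tlr6 rose by 1.61 ± 0.29, 1.47 ± 0.06 and 1.44 ± 0.07. Of 28 immediate early genes, 14 rose and 5 fell, or 15 and 5 when adjusted over the list alone (camera adjusted p = 0.00533, and adjusted p = 0.262 with an estimated correlation). Egr3, Dusp2 and Btg2 rose by 2.98 ± 0.09, 1.46 ± 0.12 and 1.30 ± 0.07.

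In central metabolism Acod1 stood apart from the rest of its list. Of 31 itaconate and tricarboxylic acid cycle genes, 4 rose and 2 fell, or 3 and 2 when adjusted over the list alone (camera adjusted p = 0.564). With total counts alone, 1 was higher and 11 were lower, and 2 were higher without IFN-γ replicate 1 or 2, with 1 lower in the latter case. Idh1, the cytosolic isocitrate dehydrogenase gene, had a log2 fold change of -0.85 ± 0.06, and the mitochondrial pyruvate carrier gene Mpc1 rose by 0.39 ± 0.08, losing its call with total counts (0.22). Of 24 glycolysis genes, 8 rose and 2 fell in both adjustments (camera adjusted p = 0.0731), against 7 and 5 with total counts. The adjusted p was 0.0263 with no filter on low counts, and 1 gene fell without untreated replicate 3 or IFN-γ replicate 3. Hk3, Pfkfb3 and Pfkp, a hexokinase and enzymes of the phosphofructokinase step, rose by 1.34 ± 0.06, 1.26 ± 0.08 and 1.13 ± 0.07. Of 37 oxidative phosphorylation genes, 2 rose and none fell, and none was called when adjusted over the list alone (camera adjusted p = 0.707). These were Cycs, at 0.31 ± 0.10, and Uqcrc2, at 0.17 ± 0.06. Both lost their calls with total counts and upper quartile scaling, and Uqcrc2 was at -0.001 with total counts and lost its call under most other settings. With total counts, 2 other genes of the list were called lower and none higher. None of the list was called without untreated replicate 1 or 3 or IFN-γ replicate 2 or 3, and 1 without IFN-γ replicate 1. Without untreated replicate 2, 12 oxidative phosphorylation genes were higher (camera adjusted p = 0.00385). That library had the steepest trend on exon length, -0.139 log2 units per doubling of length against the other 2 untreated libraries. With all libraries kept and each library's trend removed, the list stayed uncalled by camera.

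NRF2 targets, genes of the response to oxidants, were lower in 7 of 27 cases and higher in 2, in both adjustments (camera adjusted p = 0.117), and lower in 17 with total counts alone. Without untreated replicate 2, 6 were higher and 9 lower. Osgin1 and Gclc, which makes a glutathione precursor, fell with log2 fold changes of -1.15 ± 0.08 and -0.98 ± 0.07. Hmox1, the haem oxygenase 1 gene, fell from 1335 ± 104 to 726.5 ± 32.5 CPM, a log2 fold change of -0.88 ± 0.08. Of 19 HIF-1 targets, 6 rose and 5 fell in both adjustments (camera adjusted p = 0.804). Their median was -0.071, their mean 0.03 and the direction of the test down. With total counts 3 were higher and 10 lower, and 1 was lower without IFN-γ replicate 2, 2 without IFN-γ replicate 3 and 3 without untreated replicate 1 or 3. Ndrg1 rose by 1.34 ± 0.10, Hif1a by 0.94 ± 0.06, and Mxi1 fell by 0.79 ± 0.06. Of 20 LXR target and cholesterol efflux genes, 5 rose and 3 fell, or 7 and 3 when adjusted over the list alone (camera adjusted p = 0.333), against 3 and 5 with total counts. Of these genes 9 rose without untreated replicate 2, and 1 fell without untreated replicate 1 or 3 or IFN-γ replicate 2 or 3. Ch25h, which makes 25-hydroxycholesterol, rose by 4.75 ± 0.11, the sterol exporter gene Abcg1 by 0.71 ± 0.06, and the desaturase gene Scd2 had a log2 fold change of -0.69 ± 0.08. Of 24 cholesterol synthesis genes, 4 rose and 6 fell, or 4 and 7 when adjusted over the list alone (camera adjusted p = 0.735, directed down although the median was 0.001 and the mean 0.035), and 2 rose and 12 fell with total counts. Only 2 fell without IFN-γ replicate 2 or 3, and 3 without untreated replicate 1 or 3. Pmvk rose by 1.19 ± 0.08.

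Cell cycle genes formed the 1 list of 30 that was lower by camera. Of 32 genes, 19 fell and 3 rose, or 19 and 4 when adjusted over the list alone (camera adjusted p = 0.000944, and adjusted p = 0.0818 with an estimated correlation). Without untreated replicate 2, 5 rose. Cdc6, a gene of replication licensing, had a log2 fold change of -0.97 ± 0.07, while Ccnd2 and the cell cycle inhibitor gene Cdkn1a rose by 1.72 ± 0.10 and 1.51 ± 0.06. The list of replication-dependent histones was fixed as a sign of RNA quality or poly(A) selection, and 6 of its 22 listed members were tested. Of these 6, which include the replication-independent linker histone gene H1f0, 3 fell in both adjustments (camera adjusted p = 0.0568, and 0.0366 without untreated replicate 3). The log2 fold changes were -0.66 ± 0.11 for H2bc21, -0.33 ± 0.10 for H1f2 and -0.27 ± 0.06 for H1f0. Without IFN-γ replicate 2 or 3 only 1 was called, as H1f2 (adjusted p = 0.0806 and 0.101) and H1f0 (0.0512 and 0.0537) lost theirs. H1f2 also lost its call without untreated replicate 3 (0.0705) or IFN-γ replicate 1 (0.0877).

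Macrophage identity genes moved both ways. Of 29, 10 rose and 5 fell, or 12 and 5 when adjusted over the list alone (camera adjusted p = 0.187), and 6 rose and 7 fell with total counts. Beside the fall of Cx3cr1, Fcgr1, a high-affinity IgG receptor gene, rose 2.37-fold and the myeloid transcription factor gene Cebpa fell by 1.01 ± 0.06 on the log2 scale. Of 21 alternative activation genes, 8 rose and 4 fell in both adjustments (camera adjusted p = 0.336), and 5 rose and 5 fell with total counts. The lectin gene Clec10a and the interleukin-4 receptor gene Il4ra rose by 1.54 ± 0.09 and 1.31 ± 0.07. Cd163 was lower by a log2 fold change of -1.30 ± 0.24, but 21.1% of its exon bases overlap Gm52877 on the other strand. Gm52877 had a mean of 231.7 counts and Cd163 33.3, so the source of the Cd163 counts is uncertain. Arg1 was at 0.759 ± 0.0453 and 0.679 ± 0.145 CPM and was not called (adjusted p = 0.64, log2 fold change -0.16 ± 0.22). With an error this wide, a modest change either way stays open. Arg1 had a mean of 22.5 counts, and 11% of its exon bases overlap Gm40616 on the other strand, with 16.5 counts. Of 33 lysosome and autophagy genes, 8 rose and 2 fell in both adjustments (camera adjusted p = 0.187). The balance was 2 and 10 with total counts, and 17 and 3 without untreated replicate 2. Without another library 4 to 6 rose, 4 of them without IFN-γ replicate 2. Ctsc, the cathepsin C gene, rose by 1.67 ± 0.06, and Ulk1 and Ctsl had log2 fold changes of -0.40 ± 0.09 and -0.39 ± 0.09.

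Markers of other bone marrow cells were called in part. Of 16 neutrophil markers, 8 rose and none fell in both adjustments (camera adjusted p = 0.000425, and adjusted p = 0.122 with an estimated correlation). Ltf, Ngp and Csf3r rose by 1.13 ± 0.26, 0.82 ± 0.11 and 0.72 ± 0.09, and Ngp was at 9.49 ± 1.37 and 16.7 ± 0.352 CPM. Of 14 dendritic cell markers, 7 rose and none fell, or 9 when adjusted over the list alone (camera adjusted p = 0.000408, adjusted p = 0.0818 with an estimated correlation, and 0.061 with a minimum of 5 CPM in 3 samples). Kmo, Xcr1 and Ccl22 rose by 2.47 ± 0.22, 2.37 ± 0.23 and 1.39 ± 0.13, and the highest mean of these 3 was 8.09 CPM, for Ccl22 with IFN-γ. Of 5 T and NK cell markers, 3 rose in both adjustments (camera adjusted p = 0.147). Among them Il7r rose by 0.31 ± 0.06, from 247.7 to 307.8 CPM, and lost its call with total counts (0.14). With a minimum of 5 CPM in 3 samples, Il7r was the only 1 of these markers tested, so its rise alone does not tell of T or NK cells. Of 4 mast cell and basophil markers, 2 rose, or 2 with 1 lower when adjusted over the list alone (camera adjusted p = 0.336): Hdc by 2.23 ± 0.24 and Gata2 by 0.97 ± 0.13. Of 6 fibroblast and stromal markers, 2 rose in both adjustments (camera adjusted p = 0.117, but 0.0218 without untreated replicate 3 and 0.0186 without IFN-γ replicate 3). These were Vim, which macrophages also express at 3131 ± 250 CPM here, by 0.46 ± 0.07, and Pecam1, at 0.65 ± 0.19, which lost its call with total counts (0.48), upper quartile scaling and the removal of untreated replicate 1 or of IFN-γ replicate 1, 2 or 3 (0.50, 0.67, 0.56 and 0.71). Of 8 erythroid and megakaryocyte markers, 1 rose in both adjustments (camera adjusted p = 0.516), and none without IFN-γ replicate 2 or 3. Neither of the 2 B and plasma cell markers tested was called in either adjustment. Cd79b was at 4.01 and 3.30 CPM and Cd22 at 3.33 and 2.54 CPM, and both were called lower with total counts (-0.45 and -0.56) and upper quartile scaling (-0.43 and -0.54), Cd22 also without IFN-γ replicate 1 (-0.61). The mitochondrial transcript list had 0 members in the tables.

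Around Acod1, other genes within 100 kb were also higher with IFN-γ, named after their values were seen, and not every gene there is reported. On the minus strand, Gm41235 (103279911 to 103286176) overlaps the start of Acod1 but shares 0 exon bases with it. Its counts were 36, 26 and 37 untreated and 217, 187 and 205 with IFN-γ, a log2 fold change of 2.60 ± 0.13. Upstream, Kctd12 rose by 1.00 ± 0.06 from 196 CPM, Gm34643 by 1.10 ± 0.15, and 4933432I03Rik by 3.18 ± 0.57 from 0, 3 and 3 untreated counts. Downstream, Mycbp2 rose by 0.71 ± 0.16. Strand use in counting is not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart.

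**Figure D3:**
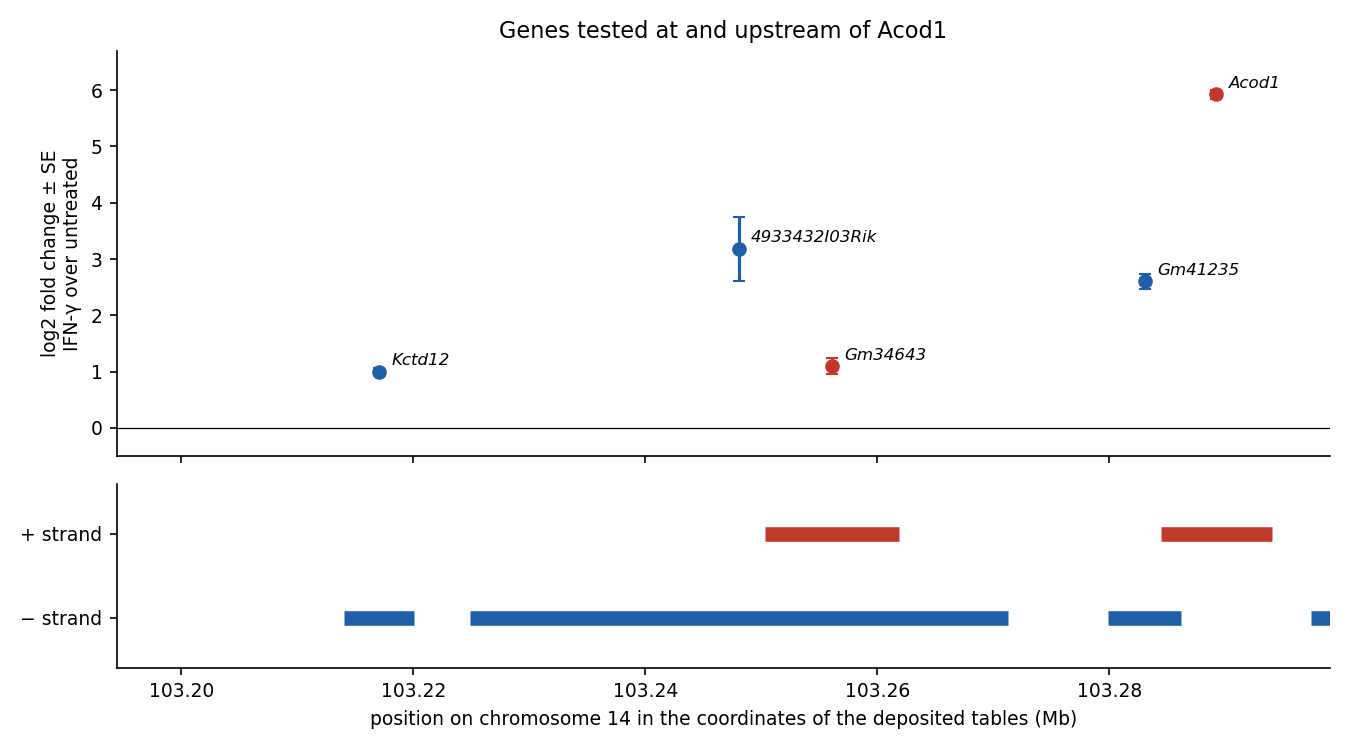
The upper panel shows the log2 fold change ± SE, IFN-γ over untreated, of the genes tested at and upstream of Acod1, each at the middle of its extent shown, and the lower panel the extent of the genes listed there on the plus strand (red) and minus strand (blue), against position on chromosome 14 in Mb in the coordinates of the deposited tables. Acod1 lies at 5.92, its neighbours between 1.00 for Kctd12 and 3.18 for 4933432I03Rik.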

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

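The correction for exon length and the fit without ribosomal RNA-like entries were chosen only after the data were seen. Acod1 kept its call under every fit that gave it a value, which leaves out the test against 2-fold. Scaling moved the counts of smaller changes: with upper quartile scaling 4097 genes were lower and 415 at least 2 times lower, and with total counts 1666 were higher, 4520 lower and 448 at least 2 times lower, against 2539, 2176 and 251. Uqcrc2 turned to -0.001 with total counts. With a minimum of 5 CPM in 3 samples, which tests 9712 genes, 498 were at least 2 times higher and 99 lower. The test against 2-fold called 506 and 55, and a threshold of 0.01 left 1242 genes lower. Camera called 14 lists higher and 1 lower, against 4 and 0 with an estimated correlation, and 24 and 3 by fry, which does not compare a list with other genes. With the replicate number as a block, 5050 genes were called, 4549 of them among the 4715, and 2 lists were lower, the histones joining at 0.0489. Same-numbered samples deviated with correlations of 0.31, 0.14 and -0.07, and not every sample correlated best with its own number, so the numbers were not taken to pair the samples. With 1 library left out, calls ranged from 3442 (without IFN-γ replicate 2) to 5967 (without untreated replicate 2), and lists lower from 1 to 2 (2 without untreated replicate 3). Of the 1051 calls at 2 times or more, 986 to 1031 were kept. DESeq2 called 4502 genes and limma-voom 4713. The causes of these differences between settings were not tested. The pseudocount alternative planned for normalized values was not run, since the tables held counts. On simulated data, with 50 genes changed at each fold, 64% of 1.5-fold changes were recovered. The simulation gave 141 calls, against 4715 here, and more calls loosen the adjusted threshold. That share therefore does not tell how many such changes were missed in these libraries.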

Other observations

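The tests of symbol families, of the smaller changes, of other splits of the samples and of the neutrophil markers were chosen only after those results were seen, while the neighbour tests were set before their genome-wide values were seen. Families of genes that share the letters of their symbol gave further groups, some of whose members are also in the fixed lists, such as Mcm2 to Mcm7 among the cell cycle genes and Parp9 and Parp14 among the type I interferon response genes. Of 223 families with at least 8 tested genes, the Mcm family, which includes the replicative helicase genes, fell in 8 of 10 cases and rose in none, with a median log2 fold change of -0.42 (camera adjusted p = 0.0117). The Klhl family, kelch-like adaptors of ubiquitin ligases, fell in 13 of 23 cases and rose in 1 (median -0.28, adjusted p = 0.0103). Of 336 zinc finger genes named Zfp, 58 fell and 25 rose, against 2176 and 2539 of all 12968 genes, so the family (median -0.12, adjusted p = 0.03) differed by fewer rises and not by more falls. On the other side, 8 of 12 Parp genes, ADP-ribosyltransferases, rose and 2 fell (median 1.64, adjusted p = 0.00277), and 7 of 8 Ms4a genes, which encode membrane proteins, rose and none fell (median 0.61, adjusted p = 0.00328). With an estimated correlation the smallest adjusted p of any family was 0.305, so none of these calls holds there. The medians of the Parp and Ms4a genes stayed above 0 with upper quartile scaling and total counts, which shift all genes down and so cannot test the direction of the falling families.

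Single values stood out between libraries of 1 group. Gapdh, chosen after its values were seen, had 956 counts in untreated replicate 3 and between 3286 and 4897 in the other 5 libraries. The ribosomal RNA-like entry AY036118, chosen likewise, had 343045 counts in untreated replicate 1 and between 16934 and 31057 in the others. Together with 5 other entries that differed in that library it held 2.38% of the counts of untreated replicate 1 and at most 0.2% of any other library.

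Of the 4715 calls, 3664 lay under 2 times, and their call and direction are the part of the result that processing could set. Untreated replicate 2 favoured short transcripts, with a slope of -0.139 log2 units per doubling of exon length against the other untreated libraries, but removing each library's trend kept 98.3% of these calls in the same direction, which argues against that trend as their source. Of the calls under 2 times, 99.7% of those lower but 49.7% of those higher kept call and direction under RLE, upper quartile and total count scaling alike. In all 880 were lost or turned, and 17 of these turned direction. But these scalings shift the median of all genes by -0.003, -0.147 and -0.17, never up, so falls could hardly be lost. For falls and rises a shift of scale and a change in RNA content therefore cannot be told apart. With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real split called 4715 genes, and it was the 1 of the 10 that gave as many. The highest of the others gave 0 with edgeR at an adjusted p under 0.05. Each of the others mixes treated and untreated libraries within its groups, which widens the spread there. Their 0 calls therefore cannot tell how many calls are false.

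Genes close to strongly induced genes tended to rise as well. Near the 117 genes at least 8 times higher, 315 other tested genes lay within 100 kb. Of these, 42.5% rose and their median log2 fold change was 0.201. It was -0.026 for the neighbours of 10000 random gene sets (permutation p = 0.0001, the smallest these sets can give). The random sets were matched on expression to the 117 genes, while the neighbours themselves were not matched. The median was 0.201 without neighbours that share exons with the induced gene and 0.166 without those that share its symbol letters, both with that p, which argues against shared exons and like-named paralogs as the whole source. Reads running on past the end of the induced gene may contribute. This was examined among the 276 neighbours left without shared exons or like symbol letters. The median of 21 first genes downstream on the same strand within 20 kb lay 0.189 above that of the other 255. With a one-sided permutation p of 0.0847 this decides nothing. Regulation shared along the chromosome is a candidate explanation, for which some remaining shift had been expected at 100 to 300 kb. That shift was not found. The median there was -0.023, against -0.026 around random sets, not above them by more than their spread (permutation p = 0.449). Sharing within 100 kb only is not tested by this and stays open.

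Of the neutrophil markers 8 of 16 were called higher, and more neutrophil-lineage cells in the treated wells may contribute. From the list, 11 granule and lineage genes were picked after the results were seen, as ones that macrophages hardly make. Over the 9 of these tested, 5 of them called, the pooled log2 fold change was 0.72 ± 0.057. Other tested markers were left out, among them Csf3r (0.72 ± 0.09) and Mmp9 (0.09 ± 0.09, named after its values were seen). A chi-square test of the spread of the 9 genes against their errors (Cochran's Q, p = 0.606) did not find different factors. With errors this wide for single genes, 1 common factor stays open for these 9, and the test does not cover the markers left out. The pooled errors, this test and the permutations below take the genes as independent. All were measured in the same 6 libraries, so shifts they share can make the pooled errors too small and Q too low. The most abundant of the 9 genes, S100a9 and S100a8, named after their values were seen, went from 42.4 and 33.6 CPM to 68.5 and 53.5 CPM. The pooled change was 0.56 ± 0.053 with total counts, which argues against scaling as the whole source. Of the 9 genes, Ltf, Prtn3 and Elane are also among the neighbours within 100 kb of genes at least 8 times higher. Prtn3 and Elane were named after their values were seen. A lower share of macrophages cannot be told apart. The mean of the 9 genes lay 0.1 above that of 39 markers of 6 other cell types (0.68 against 0.58, two-sided permutation p = 0.717). It lay 0.44 above that of the 16 B cell, erythroid and stromal markers alone (permutation p = 0.00487). The 39 include the dendritic cell markers tested, whose mean was 0.963, among them Ccl22, also in the chemokine list. Markers that the treatment may itself raise cannot measure the share of macrophages. Induction by IFN-γ within the cells present also stays open.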
